A study of Mus musculus with 12 samples.

How the data were processed

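Liver RNA from 12 mice was extracted with Trizol and enriched for polyadenylated transcripts. Stranded libraries, in which the dUTP-marked strand is not sequenced, were made by 8 cycles of PCR, per the labels' protocols. RNA integrity numbers were between 9 and 10, per the labels' protocols. The deposited table holds whole-number counts per gene for each library, not normalized, with an Ensembl gene identifier, a symbol and a gene type for each of 55421 rows. Per the submitters' processing notes, the tools were STAR 2.6.1a, RSEM, bedtools 2.27.1 and DESeq2 1.22.2 on the mouse build GRCm38 (mm10). Which tool produced the deposited counts, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counts of paralogs and of overlapping genes are uncertain for that reason. PCR copies cannot be told from independent molecules, so all counting intervals and floors cover counting error only.

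Totals ran from 16834041 to 20464807 counts per library, which was 63.4% to 90.3% of the reads over the quality limit given in the labels. Albumin took 3.54% to 9.75% of the counts. Groups came from the titles, which name the strain, genotype and replicate number. The mice were separate littermates. Chi-square tests of counts of pairs within each group found no pair within sampling noise. The Fra2 mutants carry a treatment label of 9 months against 2 months in their titles and in the design text; they were kept in their group, and an effect of age in that comparison cannot be excluded. A comparison with another strain's data, named in the design text, was not analysed here.

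Gene coordinates are from GENCODE M21 on GRCm38; 55154 of the 55421 identifiers matched without their version and 54587 with it. Analysis used R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group were kept (14076, of which 12782 are protein-coding), libraries were scaled by TMM factors, and the 12 libraries were fitted with 4 group means by the robust quasi-likelihood model. The shared fit was chosen since tissue, kit and laboratory were the same and 3 libraries per group are few. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 from glmQLFTest. The contrasts were mutants against controls in each strain, the difference of these effects (Fra2 minus Fra1) and Fra2 controls against Fra1 controls. Standard errors of log2 fold changes were derived from the test statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD. Where a group had 1 to 3 counts in sum, the ratio of summed counts is given with a 95% counting interval; where it had 0, the fold is a lower bound against 3 counts over the group.

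For 39 gene lists, camera was run with a preset correlation of 0.01, and with an estimated correlation; fry was run as a self-contained test of net direction. Adjusted p values of lists are over the 39 lists within a contrast. Adjustment over the list alone means that single genes were corrected over the list's members. The lists, tests, comparisons, alternatives and the rule for named genes were set before the data were examined. By that rule Fosl1 and Fosl2 are always named. In each strain the 10 protein-coding genes with the largest rise and the 10 with the largest fall are named if called, if the 3 mutants lay on one side of the 3 controls, and if the higher group averaged at least 1 CPM. Up to 4 called members per list with the smallest adjusted p are also named, as are up to 10 genes for the difference, up to 5 per direction for the controls, and 5 per direction called in both strains. A gene selected by this rule is not reported here. Symbols shared by several identifiers were left out, and other list members may be named where their list is described.

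The alternatives were RLE factors, no scaling factor, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of at least 1 CPM in 3 libraries, a test against a 1.5-fold change, only the libraries compared, the replicate number as a block, each library left out, and the list tests above. Leaving out Fra2 controls 1 and 2 together was added after seeing the data.

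The scripts were tested on simulated data built from the real gene means, library sizes and dispersions. In the simulated Fra1 contrast, 13933 genes were tested by edgeR. Of genes changed 4-fold, 85.9% of 64 were recovered, of those changed 2-fold 34.8% of 66, and of those changed 1.5-fold 7.46% of 67; 3 of 89 calls were false. In the simulated Fra2 contrast the shares were 81.8% of 66, 35.4% of 65 and 2.99% of 67, with 2 of 81 calls false. For the simulated difference they were 63.6% of 66, 4.48% of 67 and 0 of 66, with 2 of 47 calls false. For the simulated controls, where nothing was changed, edgeR called 0 genes and DESeq2 10. In the simulated Fra1 contrast, 22 of DESeq2's 135 calls were false, over 14076 genes. A planted list of 20 genes raised 1.5-fold was called by camera, as was 1 of 30 random lists. The simulated genes were drawn independently, so this does not show how often camera calls unchanged lists of correlated genes.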

Results

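Messenger RNA was measured in the livers of adult male C57BL/6 mice from 2 strains, Fra1hep and Fra2hep. Each strain carries a transgene for a subunit of AP-1, a transcription factor made of Fos-related and Jun-related proteins. The gene Fosl1 encodes Fra-1 and Fosl2 encodes Fra-2. Doxycycline keeps the transgene silent, and its withdrawal at weaning, 3 weeks after birth, switched the transgene on in the mutants. Littermate controls of each strain shared the cage and the withdrawal. There were 3 mutants and 3 controls per strain, 12 libraries in 4 groups, and the liver was described as mostly hepatocytes. The design text and the sample titles place sampling 2 months after induction. The treatment label of the 3 Fra2 mutants gives 9 months, whereas that of their controls gives 2 months. The age match between Fra2 mutants and controls therefore rests on the titles and the design text. Each library held between 16834041 and 20464807 counts, and 14076 of the 55421 listed genes passed the filter on low counts.

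The targeted genes were examined first. Fosl1 (ENSMUSG00000024912.6, chromosome 19, 5447547 to 5455946, plus strand, GRCm38) had 172, 193 and 252 counts in the Fra1 mutants and 0, 0 and 1 count in their controls. This was 10.8 CPM ± 1.78 (SD, n = 3) in the mutants. The summed counts, 617 against 1, gave a ratio of 588, with a 95% counting interval from 105 to 23246. Fosl2 (ENSMUSG00000029135.10, chromosome 5, 32135801 to 32157842, plus strand) reached 413 CPM ± 12.9 (SD, n = 3) in the Fra2 mutants against 25.4 ± 19.7 in their controls. The log2 fold change was 4.02 ± 0.44 (SE), with an adjusted p of 0.00185. Fosl2 did not pass the test in Fra1 mutants (log2 fold change 0.08 ± 0.42, adjusted p = 0.953), nor Fosl1 in Fra2 mutants (adjusted p = 0.847). Both mutant groups thus carried the transcript named in their label. In the Fra2 controls, Fosl2 stood at 221, 861 and 297 counts, with the highest value in replicate 2, and Fosl1 stood at 11, 1 and 1, with the highest value in replicate 1. In CPM these controls had 12.2, 48.1 and 16.0 for Fosl2, each above the 7.49 to 11.4 of the Fra1 libraries. The log2 difference of Fosl2 between Fra2 and Fra1 controls was 1.47 ± 0.41 (SE), and it did not pass edgeR's test (adjusted p = 0.866). Counts per gene cannot tell the transgene from the endogenous transcript. Fosl1 overlaps Ccdc85b on the other strand, and whether counting used strand is not given in the sources used here.

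**Figure D1:**
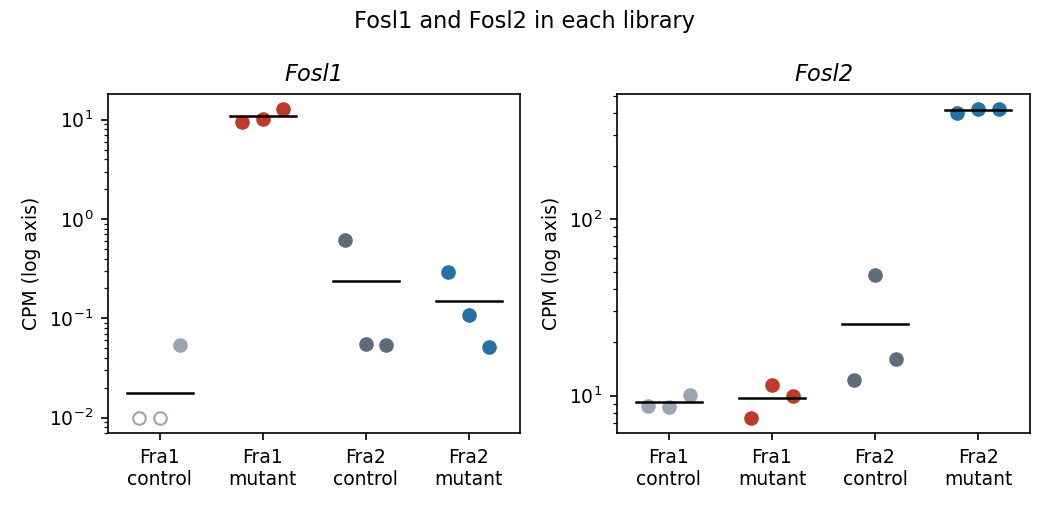
CPM of Fosl1 (left) and Fosl2 (right) on log axes in each of the 12 libraries, by group; each point is a library, the line is the group mean, and open circles at the bottom are libraries with 0 counts. Fosl1 is high in the 3 Fra1 mutants (mean 10.8 CPM) and Fosl2 in the 3 Fra2 mutants (mean 413 CPM), and Fra2 control replicate 2 lies above the other Fra2 controls for Fosl2.

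The comparison of Fra1 mutants with their controls asks what Fra-1 changes in the liver. Fra1 livers gained transcripts nearly absent from control liver. Lrtm2, a leucine-rich repeat membrane protein, rose 460-fold (95% counting interval 157 to 2233, 1449 against 3 counts). Smpdl3b, a sphingomyelinase-like membrane phosphodiesterase, went from 0.130 to 37.9 CPM ± 10.3 (SD, n = 3), a log2 fold change of 8.12 ± 0.41 (SE) with an adjusted p of 2.11e-06. Several liver metabolic transcripts fell at the same time. Hsd17b6, a steroid dehydrogenase, went from 68.3 to 1.49 CPM, and Fabp1, the main fatty acid binding protein of hepatocytes, from 7223 to 358 CPM.

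In total 408 genes rose and 132 fell in Fra1 mutants by edgeR's quasi-likelihood test, so that 75.6% of the called genes were higher. Among the largest rises, the brush-border cadherin Cdhr2 rose 278-fold (95% counting interval 94.7 to 1350) and the iron-binding protein Meltf 106-fold (29.1 to 882). Tcam1, an adhesion molecule known from testis, had 184 counts in the mutants and 0 in the controls, which makes it at least 58.4-fold higher when the control group is set at 3 counts. Inava (log2 fold change 7.64 ± 0.86, SE), the hexokinase-like gene Hkdc1 (6.45 ± 0.48), Lysmd2 (6.40 ± 0.56) and Atp6v0d2, a subunit of the vacuolar proton pump (6.39 ± 0.99), also rose. Inava was uneven among the mutants, at 19.7 CPM ± 20.1 (SD), as was Cdhr2, with 60, 581 and 234 counts in the 3 mutants. The largest falls were in the transporter Slc22a28 (-5.52 ± 0.87), Hsd17b6 (-5.50 ± 0.66), the mitochondrial acyl-CoA synthetase Acss3 (-4.55 ± 0.60) and Fabp1 (-4.33 ± 1.05). The peroxisomal fatty acid transporter Abcd2 (-3.92 ± 0.54), Dct (-3.48 ± 0.72), the water channel Aqp4 (-3.44 ± 0.83), Lcn2 (-3.26 ± 0.79), the fatty acid hydroxylase Cyp4a10 (-3.24 ± 0.74) and the carboxylesterase Ces1e (-3.22 ± 0.37) fell as well. Slc22a28, Cyp4a10 and Ces1e have close paralogs, so their counts are uncertain where reads could be split among copies.

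Of 20 measured genes of the cytoskeleton, annexin and S100 list, 6 rose in Fra1 mutants (8 when adjusted over the list alone) and none fell; the list was called by camera (adjusted p = 4.33e-09), with p = 0.00218 and an adjusted p = 0.0850 with an estimated correlation. Anxa2 (3.15 ± 0.37), its partner S100a10 (2.08 ± 0.26), Tubb6 (2.14 ± 0.33) and the hepatocyte keratin Krt8 (0.94 ± 0.19) were among them. Matrix and fibrosis genes were called as a list (adjusted p = 6.54e-06; p = 0.146 with an estimated correlation), and 2 of 28 rose (9 adjusted over the list alone), the collagen crosslinking enzymes Lox (2.44 ± 0.48) and Loxl2 (1.82 ± 0.43). Of 15 stellate cell genes, 2 rose (6 adjusted over the list alone), the small proteoglycans Dcn (0.86 ± 0.12) and Lum (1.33 ± 0.23); the list had an adjusted p of 0.00246, and its call was lost with an estimated correlation (p = 0.0318, adjusted p = 0.386). Of 12 recruited myeloid genes 1 rose (3 adjusted over the list alone), Mpeg1 (1.16 ± 0.25), and of 15 cytokine and chemokine genes 1 rose (2 adjusted over the list alone), the TWEAK receptor Tnfrsf12a (2.58 ± 0.40). Their adjusted p values were 0.00556 and 0.0433, with p = 0.122 and p = 0.109 with an estimated correlation. Of 30 cell cycle genes 1 rose, also adjusted over the list alone, the replication licensing factor Mcm2 (2.22 ± 0.23), with a list adjusted p of 0.0109 and p = 0.287 with an estimated correlation. The myeloid and cell cycle calls were lost without Fra1 mutant 2 (adjusted p = 0.105 and 0.225). The cytokine call was lost without Fra1 control 1 (0.133), control 2 (0.176), mutant 1 (0.0599) or mutant 2 (0.157).

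Of 17 genes of the NRF2 antioxidant response, 5 rose in Fra1 mutants, also when adjusted over the list alone. The list had an adjusted p of 2.57e-05, and its call was lost with an estimated correlation (p = 0.00517, adjusted p = 0.101). The 5 genes included sulfiredoxin Srxn1 (2.04 ± 0.17), the efflux transporter Abcc4 (2.36 ± 0.39), the pentose phosphate enzyme Pgd (1.32 ± 0.23) and the glutathione transferase Gsta1 (3.72 ± 0.68). In the xenobiotic metabolism list 5 of 18 rose (5 adjusted over the list alone), with Gsta2 (2.84 ± 0.19), Cyp2c55 (1.96 ± 0.38) and Abcb1a (2.04 ± 0.43). Its adjusted p was 0.0249 (p = 0.0960 with an estimated correlation), and its test and mean (0.47) were positive while its median was -0.01. The xenobiotic call was lost without Fra1 control 3 (adjusted p = 0.0930) or mutant 1 (0.145). Gsta1 and Gsta2 are near-identical copies, which makes their split uncertain. Single members of other lists rose: the AP-1 partner Mafk (1.76 ± 0.21), St14 (5.67 ± 0.71), Krt23 (2.64 ± 0.53), Ly6d (5.15 ± 1.13), Vldlr (3.25 ± 0.76), Crim1 (1.69 ± 0.23), Klf6 (1.88 ± 0.31), Perp (0.66 ± 0.12) and Asns (5.33 ± 1.12).

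Of 22 acute phase genes, which encode inflammation-responsive plasma proteins, 5 fell in Fra1 mutants (9 adjusted over the list alone) and none rose. The list had an adjusted p of 4.63e-07, and its call was lost with an estimated correlation (p = 0.0396, adjusted p = 0.386). Haptoglobin (Hp, -1.67 ± 0.29), Saa3 (-2.14 ± 0.45), Lbp (-1.38 ± 0.33) and Serpina3n (-1.63 ± 0.39) were the examples with the smallest adjusted p. The pericentral list (adjusted p = 6.54e-06; p = 0.0831 with an estimated correlation) had no single called gene over all genes tested and 3 lower adjusted over the list alone. All 14 of its members had negative log2 fold changes, among them Rgn (-1.36 ± 0.42) and Glul (-0.67 ± 0.29). Fatty acid oxidation (adjusted p = 1.39e-05; p = 0.124 with an estimated correlation) had 1 of 22 lower (4 adjusted over the list alone), Cyp4a10. Fatty acid synthesis (adjusted p = 0.000341; p = 0.159 with an estimated correlation) had none of 17 (4 adjusted over the list alone). Bile acid synthesis and transport (adjusted p = 0.000949; p = 0.0640 with an estimated correlation) had 1 of 19 lower, the bile salt export pump Abcb11 (-0.72 ± 0.14), and 7 lower and 1 higher adjusted over the list alone. Cholesterol synthesis (adjusted p = 0.00201; p = 0.278 with an estimated correlation) had 1 of 24 lower (3 adjusted over the list alone), Dhcr7 (-0.91 ± 0.17), and lost its call without Fra1 mutant 2 (adjusted p = 0.0657). The male-biased list (adjusted p = 0.00158; p = 0.248 with an estimated correlation) had none of 14 over all genes and 3 lower adjusted over the list alone. The glucose-6-phosphatase gene G6pc fell (-1.64 ± 0.35), as did Abcd2 in the female-biased list and Fabp1 in the hepatocyte identity list, none of their lists being called by camera. By fry 2 lists that camera did not call passed the test. The hepatocyte identity list was lower (adjusted p = 0.0396), and the fetal liver and liver tumour list was higher (adjusted p = 0.0369; camera adjusted p = 0.106), with 9 of 10 members positive and 1 called, Ly6d (3 adjusted over the list alone).

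With an estimated correlation, 0 of the 39 lists kept an adjusted p under 0.05 in Fra1 mutants and 4 had an unadjusted p under 0.05. The number of Fra1 genes called depended on the libraries: it was 215 higher and 52 lower without control 1, 257 and 60 without control 2, 267 and 82 without control 3, and 306 and 70 without mutant 1. Of the 59 named genes called in this comparison, 32 passed in every fit that left out a library; Fabp1, Aqp4 and Lcn2 were among the 27 that did not, with adjusted p up to 0.140 without mutant 1, 0.127 without mutant 2 and 0.127 without control 1. Without a scaling factor between libraries, 674 genes were higher and 102 lower, 86.9% higher, as the median over all genes moved from 0.01 to 0.15 on the log2 scale.

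**Figure D2:**
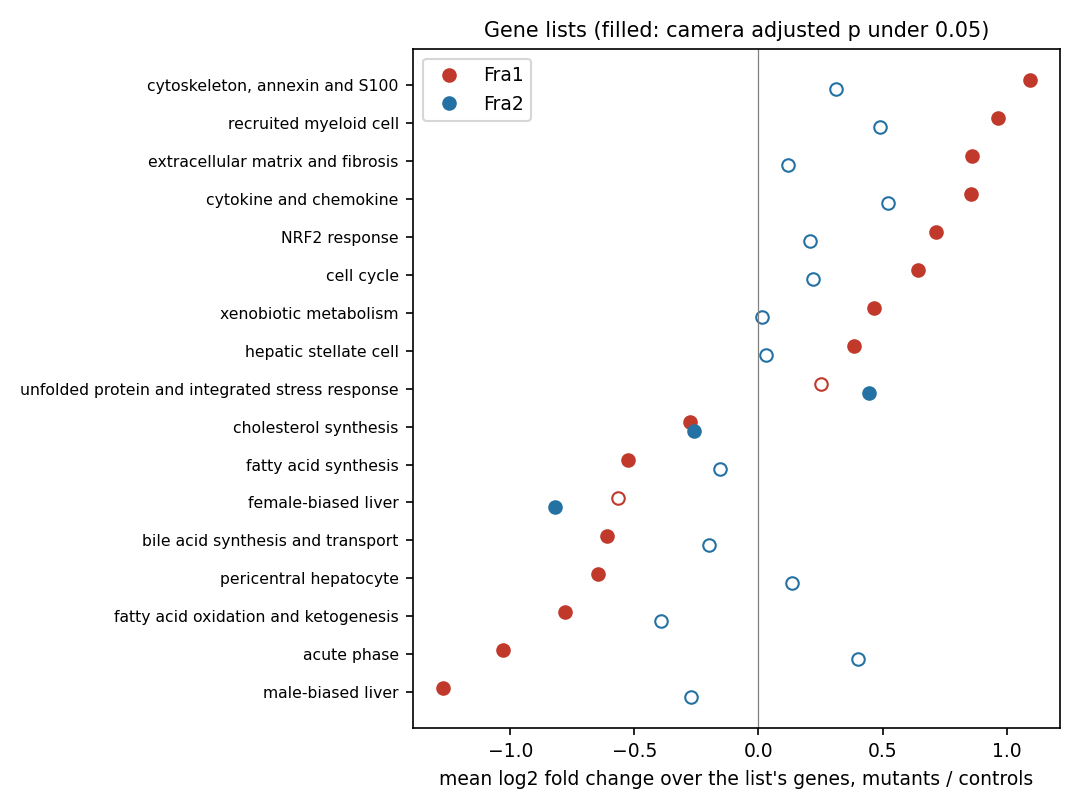
Mean log2 fold change (x axis) over the genes of each of the 17 lists called in either strain (y axis), Fra1 in red and Fra2 in blue; filled points are lists with a camera adjusted p under 0.05. Cytoskeletal genes averaged 1.10 in Fra1 and 0.31 in Fra2, and acute phase genes -1.03 and 0.40.

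The comparison of Fra2 mutants with their controls asks what Fra-2 changes. Fra2 livers also gained Lrtm2, at 23.8 CPM ± 1.69 (SD, n = 3) against 0.667 ± 0.733, a log2 fold change of 5.15 ± 0.60 (SE), and Smpdl3b (3.73 ± 0.30, adjusted p = 0.000414). They lost Abcd2 (-4.30 ± 0.55, adjusted p = 0.00420), Ces1e (-3.14 ± 0.37, adjusted p = 0.00228) and Hsd17b6 (-3.42 ± 0.57, adjusted p = 0.0183). In all, 119 genes rose and 31 fell by edgeR's quasi-likelihood test.

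The largest rises beyond these were in Tmc5 (5.86 ± 1.03), the steroid hydroxylase Cyp21a1 (4.86 ± 0.86), the lipid droplet protein Cidec (4.79 ± 0.96), the calcium-binding protein Cabp2 (4.71 ± 0.94), Arhgap22 (4.63 ± 0.52), Cdhr2 (4.26 ± 0.83), Syt14 (4.03 ± 0.48) and Fosl2 itself. Cidec ranged widely, at 73.2 CPM ± 77.3 (SD, n = 3) in the mutants. Falls were seen in Raet1d, a ligand of an activating immune receptor (-3.89 ± 0.56), Ces1c (-2.98 ± 0.56), Pbld2 (-2.72 ± 0.43), the adenylyl cyclase Adcy1 (-2.19 ± 0.41), Pir (-2.03 ± 0.24) and the zinc importer Slc39a4 (-1.61 ± 0.33). Ces1c and Ces1e have close paralogs and Raet1d overlaps Raet1e on the same strand, so these counts are uncertain.

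Among the fixed lists, 3 were called in Fra2 mutants by camera, and the number depended on the libraries: it was 15 without control 1, 5 without control 2, 6 without control 3, 9 without mutant 1, 12 without mutant 2 and 5 without mutant 3. The unfolded protein and integrated stress response list was higher (adjusted p = 0.000391, and p = 0.114 with an estimated correlation). Of its 20 members 16 were positive, none was called over all genes and 4 were higher adjusted over the list alone. These 4 were Pdia4, Calr, Dnajc3 and Sdf2l1. Of the integrated stress response genes, Atf4 (-0.21 ± 0.16), Ddit3 (-0.38 ± 0.37) and Trib3 (-0.62 ± 0.37) were negative. Chac1 (0.14 ± 0.53) and Asns (1.29 ± 0.93) were positive. None of these passed, also adjusted over the list alone, so a rise of that response is not shown. Cholesterol synthesis was lower (adjusted p = 0.00872; p = 0.277 with an estimated correlation), with 20 of 24 members negative and none called in either way. The female-biased list was lower (adjusted p = 0.0248; p = 0.0699 with an estimated correlation), and Abcd2 was the 1 of 9 members called, also when adjusted over the list alone. The unfolded protein list was also called lower in Fra2 than in Fra1 controls by camera. Its rise in Fra2 mutants therefore cannot be told apart from a low level in their controls. The cholesterol and female-biased calls were lost without Fra2 control 2 (adjusted p = 0.114 and 0.0769). The cholesterol call was also lost without Fra2 mutant 1 (0.0774). Single members of other lists rose: Srxn1 (1.75 ± 0.17), Mafk (1.25 ± 0.20), Gsta2 (1.29 ± 0.18), Mcm2 (1.85 ± 0.22), S100a10 (1.51 ± 0.26), Mpeg1 (1.51 ± 0.25), St14 (3.53 ± 0.59), Krt23 (2.78 ± 0.52), Crim1 (1.13 ± 0.23) and the male-biased Cyp4a12b (1.54 ± 0.22). Hsd17b13, a lipid droplet enzyme of periportal hepatocytes, fell (-0.92 ± 0.15).

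Fewer Fra2 genes were called on leaving out single libraries: 64 higher and 12 lower without control 2, 46 and 13 without control 3, 82 and 13 without mutant 1, 45 and 11 without mutant 2, and 46 and 7 without mutant 3. Of the 31 named genes called in Fra2, 12 passed in every such fit, among them Fosl2, Lrtm2, Smpdl3b, Arhgap22, Syt14, Srxn1, Mcm2, Abcd2, Ces1e and Pir. An alternative chosen after seeing the data, because of their Fosl1 and Fosl2 counts, left out both control 1 and control 2. It leaves only 1 Fra2 control library, which has no spread of its own, so its gene calls are not given. When each strain's 6 libraries were fitted alone, Fra2 had 71 higher and 19 lower.

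Both strains changed many of the same genes in the same direction. The 2 comparisons share no libraries, but 1 fit gave them a common estimate of each gene's spread, so their calls are not fully independent. Of the 119 genes higher in Fra2 mutants, 99 were also higher in Fra1 mutants, where independent lists would share 3.45, and of the 31 lower genes, 15 were also lower, where 0.291 would be shared (Fisher's exact test, p = 2.92e-136 and 4.46e-23; genes are not independent replicates). No gene was called in opposite directions. When each strain's 6 libraries were fitted alone, 49 genes were higher and 6 lower in both strains. Among the largest shared rises were Lrtm2, Cyp21a1 (4.39 ± 0.83 in Fra1), Arhgap22 (4.36 ± 0.55), Cdhr2 and Syt14 (5.94 ± 0.46), and the shared falls Abcd2, Hsd17b6, Ces1e, Pbld2 (-2.11 ± 0.42 in Fra1) and Adcy1 (-1.82 ± 0.43). Lrtm2 overlaps Cacna2d4 and Cyp21a1 overlaps Tnxa on the other strand. Lrtm2 lies on chromosome 6 (119315133 to 119330766), Smpdl3b on chromosome 4 (132732966 to 132757252), Abcd2 on chromosome 15 (91145871 to 91191799) and Hsd17b6 on chromosome 10 (127990936 to 128007611).

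Across the 14076 genes, the log2 fold changes of the 2 strains correlated with Pearson's r = 0.543 and Spearman's rho = 0.366, a description across genes, which are not independent. Among the 576 genes called in either strain, Pearson's r was 0.753. For the 540 genes called in Fra1, the median ratio of the Fra2 to the Fra1 log2 fold change was 0.499, and 502 had the same sign. For the 150 genes called in Fra2, the median ratio of Fra1 to Fra2 was 1.14, and 146 had the same sign. Each ratio is pulled down by the choice of genes on its denominator. Without Fra2 mutant 3, 41 genes were higher and 5 lower in both strains, and without Fra2 mutant 2 the numbers were 42 and 7. Those without Fra2 control 3 were 42 and 7, without Fra2 control 2 they were 61 and 7, without Fra1 control 2 they were 62 and 8, and without Fra2 mutant 1 they were 73 and 7.

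**Figure D3:**
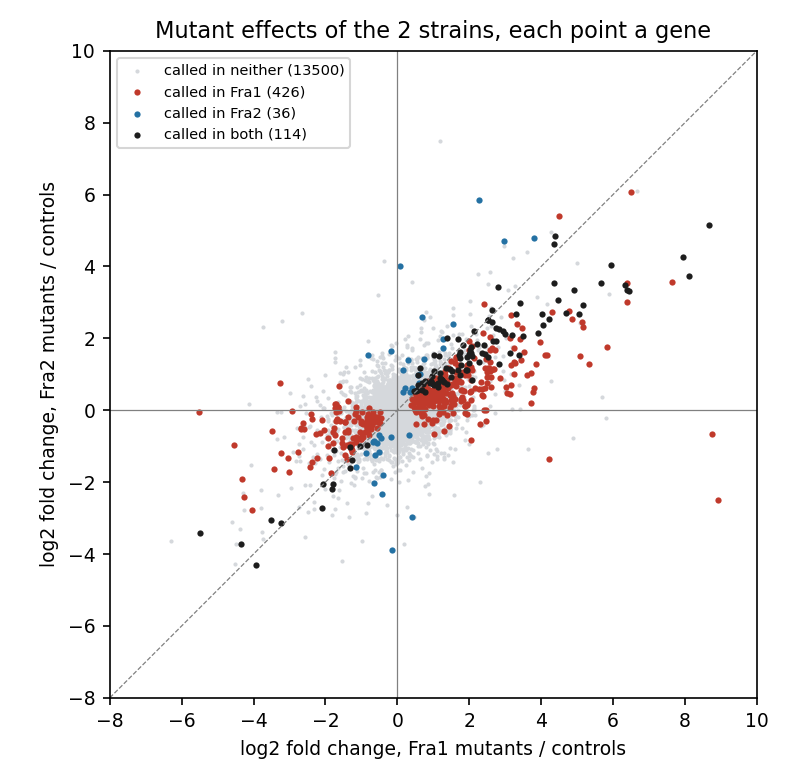
Log2 fold change of mutants over controls in Fra1 (x axis) and Fra2 (y axis) for 14076 genes, each point a gene, coloured by the strain in which it was called; the dashed line marks equal change. The 114 genes called in both strains all lie in the quadrants of equal sign.

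**Figure D4:**
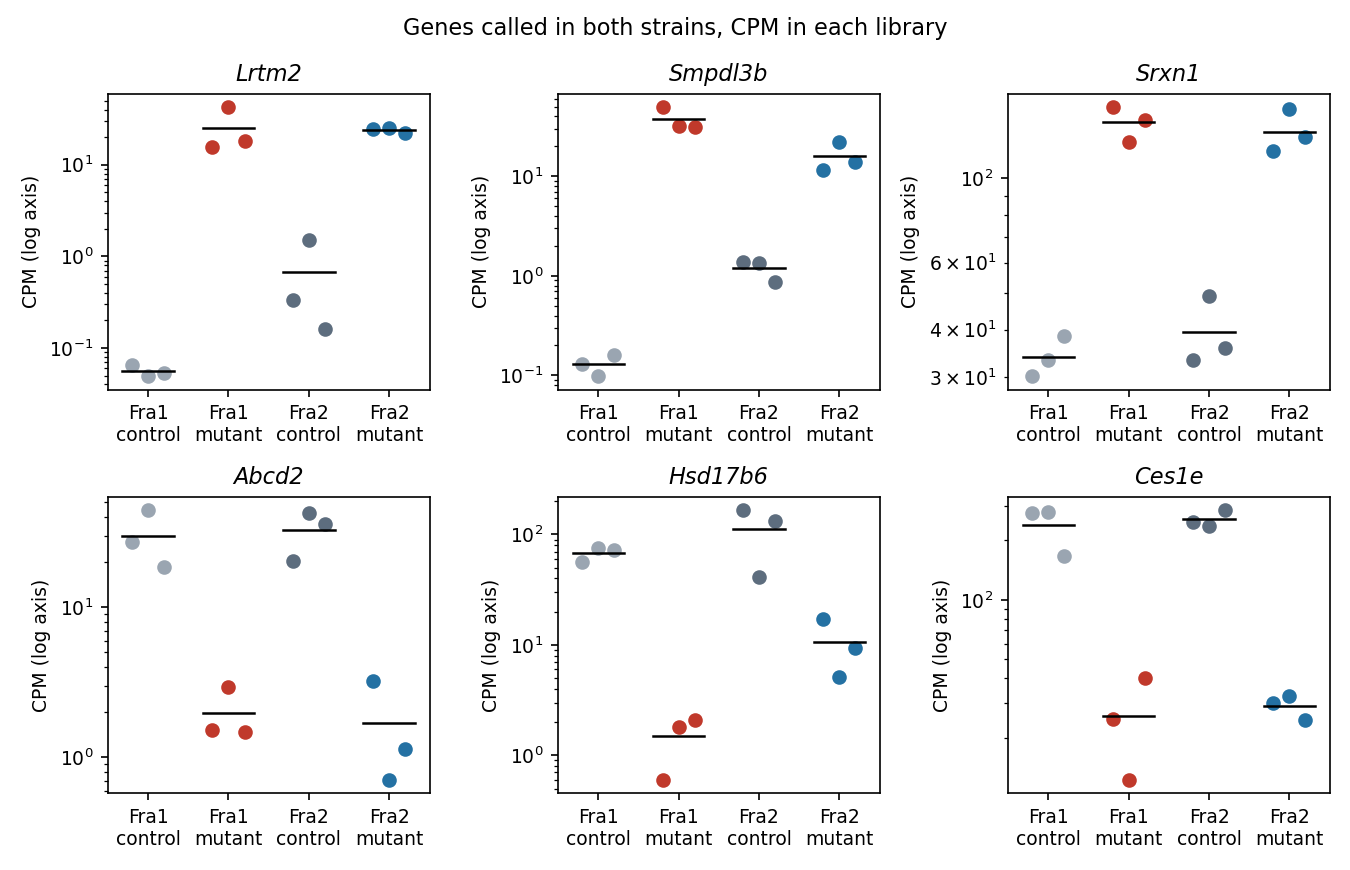
CPM on log axes of Lrtm2, Smpdl3b, Srxn1, Abcd2, Hsd17b6 and Ces1e, all called in both strains, in each of the 12 libraries; points are libraries and lines are group means. Mutants and controls of each strain do not overlap for these genes. For all but Srxn1 the rule for named genes required this, so it adds no evidence.

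Whether the strains' effects differed was tested directly, as the Fra2 effect minus the Fra1 effect. The targeted genes, each called in 1 strain only, did not pass this test. Their log2 differences were -9.41 ± 1.39 for Fosl1 (adjusted p = 0.0532) and 3.95 ± 0.59 for Fosl2 (adjusted p = 0.0612). The test thus missed large differences, and the genes passing it are not their full extent. The difference passed the test for 5 genes. Smpdl3b (log2 difference -4.40 ± 0.54, adjusted p = 0.0323), Gas7 (-1.98 ± 0.24, adjusted p = 0.0323), the actin-binding tropomyosin Tpm1 (-1.23 ± 0.17, adjusted p = 0.0394) and Dop1b (-1.29 ± 0.18, adjusted p = 0.0431) had the larger log2 fold change in Fra1 mutants. Smpdl3b went from 0.130 to 37.9 CPM in Fra1 and from 1.19 to 15.9 CPM in Fra2, and its log2 difference between Fra2 and Fra1 controls was 3.14 ± 0.49 (adjusted p = 0.277). Gas7 went from 4.86 to 125 CPM in Fra1 and from 12.5 to 81.3 CPM in Fra2, and Tpm1 from 33.2 to 139 CPM in Fra1 and from 33.2 to 59.3 CPM in Fra2. Cyp4a12b, a male-biased fatty acid hydroxylase, rose in Fra2 mutants (88.9 to 258 CPM) and stood at 66.1 against 116 CPM in Fra1 (-0.81 ± 0.21, adjusted p = 0.0643), a difference of 2.35 ± 0.31 (adjusted p = 0.0342). It has a close paralog, Cyp4a12a, so its count is uncertain.

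Acute phase genes differed between the strains by camera (mean log2 difference 1.43; adjusted p = 1.39e-13; adjusted p = 0.104 with an estimated correlation), with 20 of 22 members positive, none called over all genes and 9 higher adjusted over the list alone. Their mean log2 fold change was -1.03 in Fra1 and 0.40 in Fra2. Pericentral genes differed with all 14 members positive (0.78; adjusted p = 1.04e-08; adjusted p = 0.253 with an estimated correlation), none called over all genes and 3 adjusted over the list alone. Cytoskeletal genes differed with all 20 members negative (-0.78; adjusted p = 6.55e-06; adjusted p = 0.104 with an estimated correlation), none called over all genes and 1 lower adjusted over the list alone. In all, 18 lists were called for the difference, 6 of them with an unadjusted p under 0.05 and 0 with an adjusted p under 0.05 with an estimated correlation.

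The 5 genes were few beside the 889 of 14076 genes with an unadjusted p under 0.05, where chance alone gives a share of 0.05. Each of the 5 lost its call in at least 9 of the 12 fits that left out a library. No gene passed on leaving out any single Fra1 control, Fra1 mutant 1, Fra1 mutant 3, Fra2 control 1, Fra2 mutant 1 or Fra2 mutant 3; the count was 3 without Fra1 mutant 2, 1 without Fra2 mutant 2 and 13 without Fra2 control 3. By limma-voom 0 genes differed and by DESeq2 70.

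The controls of the strains were compared as background. No gene differed between Fra2 and Fra1 controls by edgeR (smallest adjusted p = 0.137). Of the 14076 genes tested, 753 had an unadjusted p under 0.05, a share near the 0.05 that chance alone gives. By limma-voom 0 genes were called and by DESeq2 17. Of the 39 lists, 7 were called: acute phase, unfolded protein response and pancreas, fat and mesothelium genes lower in Fra2 controls (adjusted p = 0.000153, 0.000235 and 0.0282), and xenobiotic metabolism, cell cycle, matrix and NRF2 genes higher (adjusted p = 0.000235, 0.00380, 0.0127 and 0.0298). With an estimated correlation their p values were 0.0725, 0.121 and 0.0989, and 0.0151, 0.20, 0.347 and 0.0522, and 0 of the 7 calls kept an adjusted p under 0.05. None of their members was called over all genes; adjusted over the list alone, 1 was higher in each of the xenobiotic metabolism, NRF2 and cell cycle lists and none in the other 4. Without Fra2 control 3, edgeR called 1 gene.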

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

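The tests of control libraries by shares and by immediate early genes were set before their results were seen; the splits of the samples, the low transgene activity test and both acute phase tests were chosen only after the result was seen. The values below differed between the strains' mutant effects by the test of the difference itself, given as Fra2 minus Fra1. For single genes the log2 differences were -4.40 for Smpdl3b, -1.98 for Gas7, -1.23 for Tpm1, -1.29 for Dop1b and 2.35 for Cyp4a12b.

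The lists called for the difference had these mean log2 differences. Higher in the Fra2 effect were acute phase (1.43), male-biased liver (1.00), pericentral hepatocyte (0.78), gluconeogenesis and glycogen (0.43), bile acid synthesis and transport (0.41), fatty acid oxidation and ketogenesis (0.39), fatty acid synthesis (0.37), Kupffer cell (0.32), the unfolded protein and integrated stress response (0.20) and the interferon response (0.13). Lower were fetal liver and liver tumour (-1.20), cytoskeleton, annexin and S100 (-0.78), extracellular matrix and fibrosis (-0.74), T and NK cell (-0.70), B cell and immunoglobulin (-0.63), NRF2 response (-0.51), xenobiotic metabolism (-0.45) and hepatic stellate cell (-0.36). Of all these lists, acute phase, unfolded protein, xenobiotic metabolism, matrix and NRF2 were also called between the controls, in the opposite direction. A difference between the controls therefore stays open for them. With an estimated correlation 0 of the 18 lists were called. With the preset correlation, 9 kept their call in each of the 12 fits that left out a library, and the other 9 lost it in at least 1, up to an adjusted p of 0.953 for Kupffer cell genes without Fra2 control 2.

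Other divisions of the samples were counted. With the other strain's real division kept, the real division of the 6 Fra1 libraries called 540 genes and the highest of the others 1, so that 1 of 10 splits reached the real count; for Fra2 these values were 150, 0 and 1 of 10. For the controls the real count was 0 and the highest other 1, with 10 of 10 splits at or above 0. With 10 splits no share under 0.05 can be reached. Over 100 pairs of splits, 1 (the real one) gave 114 genes called in both strains, against 0 for the highest other. Of the 99 other pairs, 98 called no gene in at least 1 strain, which fixes their overlap at 0, so this count decides nothing about the overlap. For the correlation 1 of the 100 pairs, the real one, gave a value as large as 0.543, against 0.368 for the highest other. Most other pairs keep neither strain's real division, which weakens any mutant effect in both. With the Fra1 division kept, the highest other value was 0.334, and with the Fra2 division kept it was 0.368. Those are 10 splits each, too few for a share under 0.05, so chance is not excluded for the correlation. For the difference, 100 of 200 ways to deal out the strain labels within genotype were drawn: 2 gave 5 or more genes, the real one included, and the highest other also gave 5. These draws mix mice of both strains within a group, which adds any strain difference to the spread and can lower the count. The share of 2 in 100 therefore does not exclude chance for that count.

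The number of lists called did not stand apart from other divisions. Between the controls it was 7, against 21 for the highest other split. In Fra1 it was 15 against 16 for the highest other split, with 3 of 10 splits as high, and in Fra2 it was 3 against 17, with 9 of 10 as high; 10 splits are too few for a share under 0.05. For the difference it was 18 against 19, with 7 of 100 draws as high, so chance is not excluded.

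Fosl2 stood at 12.2 and 16.0 CPM in Fra2 controls 1 and 3, already above the Fra1 libraries (7.49 to 11.4 CPM). Fra2 control 2 had 861 Fosl2 counts against 221 and 297 in these baseline controls, a share of 8.51% of the way to the mutant level. Induction of the endogenous gene with the stress-responsive immediate early genes is argued against, since that list's median log2 ratio in this library was -0.23, with 6 of 17 genes higher. Over 29 other genes raised at least 4-fold in Fra2 mutants, the median share was 8.13% (95% bootstrap interval 3.38 to 11.8). These genes were chosen against Fra2 controls 1 and 3, which also set the baseline of the share. A share above 0 can therefore arise without mutant RNA. RNA or reads of Fra2 mutants in this library remain possible but are not shown by this share. Low activity of the transgene in that control cannot be told apart from this, since target genes would rise under both; 5 genes nearly silent in Fra1 controls had pooled shares of which the lowest over the 3 mutants was 6.93% (41 counts, 95% counting interval 4.97 to 9.40). Lrtm2 gave 27 of these 41 counts, with 6 and 3 in Fra2 controls 1 and 3, so the pooled share rests mostly on that gene. Cdhr2 had 3 counts in Fra2 control 2, against 3 and 2 in the others. Without Fra2 control 2, Fra2 had 64 higher and 12 lower genes.

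Fosl1 had 5, 2 and 1 counts in the Fra2 mutants. The 95% counting interval of mutant 1 (1.62 to 11.7) overlapped that of Fra2 control 1 (5.49 to 19.7). Control 1 had 11 Fosl1 counts, where the Fra1 transgene is not expected, against 1 count in each other Fra2 control. This was 5.15% of the way to the Fra1 mutant level, and 133 other genes raised at least 4-fold in Fra1 mutants had a median share of 6.33% (95% bootstrap interval 3.12 to 10.3), so some Fra1 mutant RNA or reads in this library remain possible. Tcam1, with 12 counts in this library and 0 and 1 in the other Fra2 controls, stood 19.6% of the way (95% counting interval 9.74 to 34.9, against 2.31 to 9.61 for Fosl1), and these intervals leave out the spread among the Fra1 mutants, which had 24 to 88 Tcam1 counts. The pooled share of 15 genes nearly silent in Fra1 controls depended on the source taken: it was 6.75% of mutant 1, 2.31% of mutant 2 (95% counting interval 1.78 to 2.95) and 5.74% of mutant 3. An immediate early response stays open, as that list's median log2 ratio was 0.00213 with 9 of 17 genes higher, and no biological explanation beyond this was tested.

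The acute phase list was called lower in Fra1 mutants (5 of 22 members called, 9 adjusted over the list alone) and different between the strains' effects (none called, 9 adjusted over the list alone), and with an estimated correlation both calls were lost (p = 0.0396, adjusted p = 0.386, and p = 0.00915, adjusted p = 0.104). By camera with the preset correlation, the largest adjusted p over the 12 fits without 1 library was 3.42e-09, so that call for the difference did not rest on 1 library. Whether the list differs at all stays open, since the call was lost with an estimated correlation. A difference between the strains' controls alone stays open: the list was lower in Fra2 than in Fra1 controls (mean log2 difference -0.48, 20 of 22 members, none called; adjusted p = 0.000153; p = 0.0725 with an estimated correlation), while between the mutants it was 0.95 higher in Fra2, with 17 of 22 members (camera adjusted p = 1.61e-06; p = 0.0535 with an estimated correlation). The list's mean log2 level, from each gene's mean over the libraries, was -0.89 to -0.39 in the Fra1 mutants and -0.10 to 0.72 in the Fra2 mutants, and chance keeps 3 against 3 apart in 10% of cases. A different action of Fra-1 and Fra-2 is one biological explanation that the groups allow. The mutants also differed in the level of the induced transcript, higher for Fosl2 than for Fosl1, which the groups cannot separate from it. Both stay untested, as does the age given in the Fra2 mutants' treatment label.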

How the results depend on the processing

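No call of a named gene changed direction under the alternatives. Each setting moved the counts as follows, and the cause was not tested except where fewer libraries or a fold threshold set it. Leaving out single libraries gave 215 to 334 higher and 52 to 110 lower genes in Fra1, 45 to 84 and 7 to 29 in Fra2, 41 to 105 and 5 to 17 in both, 0 to 13 for the difference and 0 to 1 for the controls, a correlation of 0.431 to 0.551, and 14 to 20, 5 to 15 and 14 to 18 lists in Fra1, Fra2 and the difference. DESeq2 gave 674 and 331 in Fra1, 311 and 130 in Fra2, 218 and 59 in both, 70 for the difference, 17 for the controls and a correlation of 0.167 over all genes with a value, against 0.543 over the 14076 genes. The 1.5-fold threshold gave 172 and 25, 33 and 7, 30 and 4, and 0. Without a filter the difference had 9 genes, the controls 3, and the correlation was 0.116, low-count genes being included. Without a scaling factor Fra1 had 674 higher. By limma-voom the difference had 0. With only the libraries compared, Fra2 had 71 and 19, both strains 49 and 6, and Fra2 6 lists. RLE factors gave 5 Fra2 lists. With an estimated correlation 0, 0 and 0 lists were called, and by fry 7, 0 and 0. Without Fra2 controls 1 and 2 (chosen after seeing the data), only 1 Fra2 control library is left, which has no spread of its own. The spread in that fit comes from the other groups, so its 16 Fra2 lists decide nothing. The mean log2 fold change of gluconeogenesis in Fra2 (-0.33) and the mean log2 difference of AP-1 genes (0.14) turned direction there. Neither list had been called with all libraries.

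Replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.12 to 0.06. With the number as a block, Fra1 had 83 lower genes, Fra2 78 higher and 20 lower, both strains 59 higher, and Fra2 13 lists. At this depth and with 3 libraries per group, 1.5-fold changes were mostly not recovered in simulated data (7.46% in Fra1).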

Other observations

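The count of Fra2-called genes among the controls was chosen after the result was seen; the list tests were planned. Several cell types and processes that the comparisons above did not describe showed no list call in either strain. Kupffer cell genes had a mean log2 fold change of -0.07 in Fra1 (adjusted p = 0.680; p = 0.851 with an estimated correlation) and 0.26 in Fra2 (adjusted p = 0.177), and 0 of 12 members were called in either, also when adjusted over the list alone. Liver endothelium genes stood at 0.11 and -0.12, with 0 of 16 members called in either strain. T and NK cell genes had all 12 measured members positive in Fra1 (mean 0.66, adjusted p = 0.0546) and 5 of 12 in Fra2 (mean -0.04, adjusted p = 0.871). Glycolysis genes (adjusted p = 0.574 in Fra1 and 0.871 in Fra2) and mitochondrially encoded genes (mean log2 fold change -0.15 in both) did not pass the test either.

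The share of counts taken by albumin, the most abundant hepatocyte secretory transcript, was 7.09% ± 0.942 (SD, n = 3) in Fra1 controls and 5.87% ± 2.32 in Fra1 mutants, and 8.88% ± 1.23 in Fra2 controls and 4.45% ± 0.913 in Fra2 mutants. These shares were not tested.

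Between the controls edgeR called 0 genes, limma-voom 0 and DESeq2 17. By edgeR 753 of the 14076 genes tested had an unadjusted p under 0.05 there, a share near the 0.05 that chance alone gives. Of the 119 genes higher in Fra2 mutants, 85 were also higher in Fra2 controls than in Fra1 controls, with a median log2 difference of 0.19. Choosing genes by the Fra2 comparison favours low values in Fra2 controls, which works against this direction. Smpdl3b had 25, 24 and 16 counts in the Fra2 controls and 2, 2 and 3 in the Fra1 controls. Of the 31 genes lower in Fra2 mutants, 24 were also higher in Fra2 controls, a direction that this choice of genes favours.

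On the first principal component, with 29.8% of the variance, Fra1 mutants (32.2 to 55.9) and Fra2 mutants (7.73 to 24.7) lay apart from the 6 controls (-40.3 to -18.5). Fra1 mutant 2 was the library with the highest value on the second component (46.0).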
